A study of Mus musculus with 13 samples.

How the data were processed

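Spatial transcriptomes of 13 mouse liver sections were analysed, 6 from mice on standard chow and 7 from mice on a diet that induces non-alcoholic steatohepatitis (NASH), a fatty liver disease with inflammation and fibrosis. The diet, a choline-deficient, amino acid-defined, high-fat formula, held 45% of its calories as fat and 28% as fructose, with 1% cholesterol and 0.1% methionine, and was fed for 8 to 12 weeks. Per the series' design text, the male C57BL/6 mice were 7 to 10 months old, and 3 chow mice and 4 NASH mice gave 2 sections each, which makes 14. The titles number the 13 sections used here as biological replicates of each diet (Bio Rep) and give no mouse identifiers. This differs from the design text, which is followed here. By it, some sections of a group share a mouse. The p-values of every test over all sections are therefore too small, and they measure the spread between sections, which is partly technical.

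Fresh-frozen sections were permeabilized for 18 to 24 minutes on Visium slides, per the labels' protocols, and polyadenylated RNA was captured on barcoded spots. A Visium spot is a small round region of tissue that holds several cells, so all values refer to regions and none to cell types. The deposited matrices hold unnormalized counts of unique molecular identifiers (UMIs) per gene and spot, made by the authors with Space Ranger 1.3.0 against GRCm38, per the submitters' processing notes. The values are whole numbers, and the files list only barcodes that the position tables place over tissue. The annotation version and sequencing settings are not given in the sources used here. Each matrix has 32338 features, of which 22 name vector or reporter sequences. These 22 were left out of library sizes and tests; the highest count of any of them in a section was 4. Another 49 symbols belong to several gene identifiers and were kept apart by identifier. Gene coordinates come from a RefSeq table of the same build, matched by symbol; 14196 of the 14624 genes tested by diet had a match.

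Section totals ran from 20150469 to 64844238 UMIs over 1396 to 3184 spots. In data simulated at these depths and spreads, with 200 genes changed in each comparison, the diet test recovered 38% of the 1.5-fold and 76% of the 2-fold changes, with 1 false call among 14624 genes. The test of the zonation difference recovered 68% and 88%, with 6 false calls among 13700 genes. In the real data the diet test called 9665 genes, far more than the 200 changed here, and sections share mice. The simulated sections were independent, so these rates need not hold for the real tests. Intervals and SDs cover the sections only. No section pair agreed within sampling noise: the lowest chi-square statistic per degree of freedom between sections was 18.2, so none was counted as a duplicate.

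For the comparison by diet, counts were summed over all tissue spots of a section and tested with edgeR 4.0.16 (quasi-likelihood test, filterByExpr, TMM scaling, limma 3.58.1, R 4.3.3). Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD over sections; log2 values are given ± SE, NASH over chow. TMM factors ran from 0.635 to 0.796 in chow and from 1.19 to 1.49 in NASH. Scaling by total UMIs alone raised the median log2 value of all genes from 0.03 to 0.91. Directions in the report are thus relative to the median gene, not to the RNA total of a section.

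Liver lobules run from the portal vein (portal zone) to the central vein (central zone). Spots with at least 500 UMIs were ranked within each section by a score from 8 central landmark genes (Cyp2e1, Cyp1a2, Slc1a2, Gulo, Cyp2c37, Rhbg, Lect2, Mgst1) minus 8 portal ones (Cyp2f2, Hal, Hsd17b13, Ctsc, Aldh1b1, Cdh1, Pigr, Sds). The score used z-scored ln(1 + counts per 10000). Spots were divided by this score into 3 groups of equal size, and the highest and lowest groups are called the central and the portal zone. Counts summed per zone gave 26 libraries, fitted in edgeR with section as a block and a central over portal term for each diet; the difference between the terms is the zonation difference, NASH minus chow. Genes of this landmark set were left out and were measured in zones ranked by a second set, with Glul, Oat, Cyp2c29, Cyp2c50, Rgn, Cyp2a5, Gstm3 and 1 gene that is not reported here by name as central and Ass1, Asl, Gls2, Uroc1, Pck1, Hsd17b6, Etnppl and Arg1 as portal genes. Ctsc is also expressed by macrophages.

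Spatial measures used spots thinned to 5000 UMIs, leaving out shallower spots: 0.349% to 2.75% of spots in chow sections and 0.956% to 25.7% in NASH sections. They are the Pearson correlation between the scores of both landmark sets, Moran's I of the joint score over adjacent spots, and Spearman's rho across spots between list scores and the landmark score or another list score. Groups were compared by two-sided exact permutation over the 1716 splits of 13 sections into 6 and 7; the smallest p this allows is 0.00117. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

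Before the data were examined, 42 gene lists were fixed, 16 of markers of liver cell types and 26 of functions, along with the designs, the alternatives and the rule for named genes. By diet the rule took the 12 genes with the largest log2 change in each direction among those with an adjusted p below 0.05, a mean log2 CPM of at least 4 and no overlap between sections of the diets. Unnamed gene models and haemoglobin, immunoglobulin and mitochondrial genes were left out. For zonation it took the 8 most central and 8 most portal genes in chow and the 8 largest differences each way at a mean log2 CPM of at least 5, and all 32 landmarks. Members of a list were taken by lowest p, some of which are not reported here. Members named only as exceptions in a list were chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists tested.

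File names carry library numbers in 2 consecutive runs: chow sections 1 to 3 and NASH sections 1 to 3 form number block 1, and chow sections 4 to 6 and NASH sections 4 to 7 form number block 2. The blocks are treated as possible library batches. Both diets share replicate numbers 1 to 6. Deviations of same-numbered sections from their group means correlated at 0.209 to 0.644 across 5437 genes, so a fit with the number as a block was compared. By these deviations from group means, 2 of the 6 chow sections correlated best with the NASH section of their own number. The relation comes from the number blocks: taken within blocks, the correlations of same-numbered sections ran from -0.328 to 0.274. Within a diet, sections n and n + 3 deviated together: taken within blocks, their correlations were 0.293 to 0.731, against -0.453 to 0.274 for the other pairings across blocks, and of 144 ways to match the sections across the blocks 1, this one, gave correlations as high. The matching was chosen after these deviations were seen, so its rank is no independent test of it. Library numbers run in the same order of diets in both blocks. Sections n and n + 3 were therefore taken as likely sections of 1 mouse, with NASH section 7 alone, as an alternative (3 and 4 likely mice); the labels do not state this.

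Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, only spots of at least 3000 UMIs, the replicate block, a number block term, each number block alone, each section left out in turn, mitochondrial genes left out, thinning to the smallest section, the second landmark set for the zones, the outer groups of 4, scores averaged over adjacent spots, thinned spots, and thinning to 2000 UMIs or none. Added after seeing the data were counts summed or values averaged per likely mouse, total UMI scaling, section quality within blocks, the diet comparison without NASH sections 4 to 7 (each with over 10% of spots below 5000 UMIs), a diet by number block interaction, and chow zonation taken in one number block and compared in the other. No clustering, deconvolution or doublet calling was done, and tissue images were not used here.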

Results

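Spatial gene expression was measured in 13 liver sections of male C57BL/6 mice, 6 from mice on standard chow and 7 from mice on the NASH diet, a choline-deficient high-fat formula that induces steatohepatitis. The study asked how the zonation of gene expression across the liver lobule is perturbed in this model. The authors' UMI counts per gene and Visium spot, a small region holding several cells, were used as deposited. Sections held 1396 to 3184 spots and 20150469 to 64844238 UMIs. The median depth per spot was 22535 ± 7232 UMIs in chow (SD, n = 6) and 15300 ± 7880 in NASH (n = 7), with p = 0.113 in a two-sided exact permutation test and an adjusted p of 0.339 over 3 quality measures. The median number of genes per spot was 3683 ± 516 and 3992 ± 894 (exact p = 0.5, adjusted p = 0.662). Mitochondrial genes took 2.89% ± 0.603 and 2.66% ± 1.15 of the counts (exact p = 0.662). Within number block 1 this share was 2.84% in 3 chow and 3.89% in 3 NASH sections (exact p = 0.1, the smallest that 3 against 3 allows). Within number block 2 it was 2.93% in 3 chow and 1.73% in 4 NASH sections (exact p = 0.0571, the smallest that 3 against 4 allows). Since sections share mice, these p-values are too small.

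The first comparison asked which genes differed between diets over whole sections. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose from 0.471 ± 0.279 to 600 ± 124 CPM (SD, n = 6 and 7), a log2 change of 10.32 ± 0.35 (adjusted p = 9.5e-12). It lies on GRCm38 chromosome 6, from 49036518 to 49058182. The macrophage elastase gene Mmp12 rose by 7.91 ± 0.32, the lipid receptor gene Trem2 by 5.80 ± 0.31, the integrin gene Itgax by 5.26 ± 0.21 and the osteoclast and macrophage proton pump gene Atp6v0d2 by 5.38 ± 0.12. The matrix protease genes Mmp7 and Adam8 rose by 5.63 ± 0.33 and 6.57 ± 0.20, and the protease inhibitor gene Timp1 by 5.13 ± 0.29. Ly6d rose by 6.81 ± 0.22, the recombination gene Rad51b by 6.43 ± 0.33, the ubiquitin-like modifier gene Ubd by 5.22 ± 0.26 and the female-biased cytochrome gene Cyp2a4 by 7.25 ± 0.64. Cyp2a4 has a near-identical paralog, Cyp2a5, so its counts are uncertain.

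Among the genes that fell, 8 of the 12 named were major urinary proteins, the pheromone carriers that male mouse liver secretes. Mup11, on chromosome 4 from 60658466 to 60662432, dropped from 17420 ± 6007 to 34.9 ± 12.4 CPM and fell by 8.96 ± 0.35 on the log2 scale (adjusted p = 3.4e-11). The others were Mup7 (-8.82 ± 0.67), Mup17 (-8.22 ± 0.35), Mup16 (-7.68 ± 0.41), Mup9 (-6.73 ± 0.38), Mup1 (-6.52 ± 0.37), Mup18 (-6.05 ± 0.21) and Mup12 (-5.70 ± 0.36). Mup genes are near-identical copies, and so is the antitrypsin gene Serpina1e (-5.93 ± 0.37) to its neighbours, so the split of counts within each family is uncertain. The steroid dehydrogenase gene Hsd3b5 fell by 8.30 ± 0.34, from 149 ± 65.7 to 0.478 ± 0.175 CPM, and the organic anion transporter gene Slco1a1 by 5.88 ± 0.22. Moxd1, a monooxygenase gene, had 38621 UMIs over the chow sections, at 0.452 to 265 unscaled CPM per section, and 4 UMIs over the NASH sections, of which 3 had none (adjusted p = 4.6e-06). Its chow level rests on 4 of the 6 sections, at log2 CPM 8.02 to 8.41. Chow sections 2 and 5, likely from 1 mouse, stood far below these at 0.28 and -0.69, though above every NASH section (-3.54 or lower).

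All 10 lipid-associated macrophage genes were higher in NASH (median log2 4.48; adjusted p = 0.0425 with an estimated correlation), and so were all 8 monocyte and macrophage genes (median 3.16; adjusted p = 0.0813 with an estimated correlation). In the latter list the lysozyme gene Lyz2 rose by 3.68 ± 0.17, Ccr2 by 3.35 ± 0.21 and Cd68 by 3.06 ± 0.23. Kupffer cell genes, which mark the resident macrophages, split. Timd4 fell by 3.46 ± 0.32 and Marco by 2.68 ± 0.51, Adgre1 rose by 1.90 ± 0.19 with Cd5l and Folr2, and Clec4f and Vsig4 did not pass. The median of the 7 was 0.22 and their mean -0.37, of opposite sign (adjusted p = 0.939 with an estimated correlation). Other immune lists rose in most members. Of 9 T and NK cell genes 8 rose, among them Cd8a by 4.54 ± 0.29 and Nkg7 by 2.50 ± 0.25 (adjusted p = 0.32 with an estimated correlation). Of 5 B and plasma cell genes 4 rose (among them Cd79b by 2.04 ± 0.14, Cd79a by 1.52 ± 0.19 and Ms4a1; adjusted p = 0.205 with an estimated correlation). All 6 dendritic cell genes rose (Ccr7 by 3.75 ± 0.35, Cd209a by 2.88 ± 0.30; adjusted p = 0.0769 with an estimated correlation). Of 6 neutrophil genes 4 rose (Csf3r by 2.72 ± 0.18, S100a8 by 0.67 ± 0.20, S100a9 and Cxcr2) and Retnlg fell by 0.98 ± 0.26 (adjusted p = 0.626 with an estimated correlation). At total UMI scaling 5 neutrophil genes were higher and 0 lower, with Retnlg at -0.09. S100a9 did not pass within number block 1 (0.16), without NASH sections 4 to 7 (0.26), or without chow section 1 (0.38), 4 (0.37) or 5 (0.36) or NASH section 3 (0.39). Adjusted over the list alone, 5 neutrophil genes rose; for the other lists of this paragraph the counts adjusted over the list alone were the same.

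All 7 MHC class II genes rose (median 2.69; Ciita by 3.61 ± 0.21, Cd74 by 2.68 ± 0.20; adjusted p = 0.137 with an estimated correlation). Of 14 interferon-response genes 13 rose, with Ifi44 at 3.51 ± 0.28, Oasl2 at 3.20 ± 0.26 and Usp18 at 3.07 ± 0.27 (adjusted p = 0.311 with an estimated correlation). Of 14 chemokine and inflammation genes 10 rose, among them Ccl5 by 3.38 ± 0.22, Ccl4 by 3.55 ± 0.24 and Cxcl16 by 1.72 ± 0.13, and Cxcl1 fell (adjusted p = 0.202 with an estimated correlation). Proliferation genes rose in 15 of 16 cases, with Ccna2 at 3.30 ± 0.17, Top2a at 3.32 ± 0.18 and Mki67 at 3.03 ± 0.18 (adjusted p = 0.0759 with an estimated correlation). Of 11 p53-response genes 7 rose, such as Phlda3 by 2.50 ± 0.18 and Tnfrsf10b by 2.58 ± 0.20 (adjusted p = 0.182 with an estimated correlation); at total UMI scaling all 11 were higher. Of 14 oxidative stress genes 9 rose, such as Cbr3 by 2.88 ± 0.19, Gstm3 by 2.68 ± 0.18 and Srxn1 by 1.35 ± 0.09, and Gclm, Txnrd1 and Ugdh fell (adjusted p = 0.0813 with an estimated correlation); at total UMI scaling 13 rose and 0 fell. With p adjusted over the list alone, 2 chemokine genes fell, and the other counts of this paragraph were the same.

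All 22 extracellular matrix genes rose (median 2.82; adjusted p = 0.0813 with an estimated correlation). The collagen genes Col6a3 and Col3a1 rose by 3.28 ± 0.13 and 3.52 ± 0.18, and Fstl1 by 3.05 ± 0.17. All 8 cholangiocyte genes, markers of bile duct epithelium, rose (median 2.77; Epcam by 3.86 ± 0.23, Cldn7 by 2.86 ± 0.23, Tspan8 by 3.52 ± 0.28; adjusted p = 0.137 with an estimated correlation). All 6 portal fibroblast genes tested rose (Eln by 4.41 ± 0.31, Dpt by 2.87 ± 0.24; adjusted p = 0.137 with an estimated correlation). Of 9 stellate cell genes, markers of the vitamin A-storing mesenchymal cells, 7 rose (among them Lrat by 1.27 ± 0.12 and Dcn by 1.29 ± 0.13) and Ecm1 fell (adjusted p = 0.437 with an estimated correlation). At total UMI scaling 8 were higher and 0 lower. Of 5 smooth muscle genes Tagln rose by 0.84 ± 0.14 and Myh11 fell by 0.95 ± 0.28 (adjusted p = 0.94 with an estimated correlation). Myh11 did not pass within number block 2 (-0.33) or at total UMI scaling (-0.03), where 2 of the 5 were higher. Of 9 sinusoidal endothelial genes 6 fell, among them Kdr by 1.09 ± 0.13, Oit3 by 0.88 ± 0.13 and Dnase1l3 by 1.15 ± 0.22, but at total UMI scaling 4 of the 9 were higher and 0 lower (adjusted p = 0.554 with an estimated correlation). Of 6 genes of Wnt-secreting venous endothelium Wnt2 fell by 1.04 ± 0.19, Thbd by 0.60 ± 0.15 and Wnt9b by 0.87 ± 0.21, and Rspo3 rose, though not within number block 1 (0.35) or with counts summed per likely mouse, sections n and n + 3 of a diet (0.32). At total UMI scaling 3 of the 6 were higher and 0 lower (adjusted p = 0.694 with an estimated correlation). Wnt9b did not pass within number block 1 (-0.73) or without NASH sections 4 to 7 (-0.65), nor Thbd within number block 2 (-0.44). Of 5 erythroid genes Alas2 fell by 1.53 ± 0.21 and the globin genes did not pass (adjusted p = 0.626 with an estimated correlation), except Hbb-bs without NASH section 5 (-1.11). Msln, the 1 mesothelial gene tested, was at 0.77 ± 0.50 (adjusted p = 0.19), but passed without chow section 2 (1.29), within number block 2 (1.68) and at total UMI scaling (1.65); over all settings its adjusted p ran from 0.00648 to 0.621. Among these lists, counts adjusted over the list alone differed for sinusoidal endothelial genes, of which 1 rose.

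All 20 cholesterol synthesis genes were lower (median -2.69; adjusted p = 0.0425 with an estimated correlation), led by the squalene epoxidase gene Sqle (-5.25 ± 0.18), Cyp51 (-4.16 ± 0.15) and Nsdhl (-3.85 ± 0.15), and 18 of them were lower at total UMI scaling too. All 12 male-biased liver genes fell (median -4.28; adjusted p = 0.0425 with an estimated correlation), Mup3 by 4.69 ± 0.19, and all 12 were lower at total UMI scaling. Of 5 female-biased genes tested 4 rose, among them Cyp2b9 by 6.09 ± 0.54, Cyp2b13 and Acot3, and Cyp17a1 fell by 2.50 ± 0.29 (adjusted p = 0.531 with an estimated correlation). Of 12 fatty acid synthesis genes 9 fell, with Me1 at -2.74 ± 0.20, Acly at -1.99 ± 0.17 and Acacb at -2.01 ± 0.18 (adjusted p = 0.137 with an estimated correlation); at total UMI scaling 6 were lower and 2 higher. Lipid droplet genes went both ways: Cd36 rose by 2.37 ± 0.12 and Plin4 by 1.64 ± 0.24, with Cidec and Hilpda, and 7 of the 13, such as Dgat2 by 0.94 ± 0.12, fell (median -0.42; adjusted p = 0.936 with an estimated correlation), while at total UMI scaling 7 were higher and 0 lower. Of 21 fatty acid oxidation genes 11 fell, such as Acaa2 by 1.52 ± 0.10 and Acadvl by 1.07 ± 0.09, and Cyp4a10, Cyp4a14 and Pdk4 rose (adjusted p = 0.348 with an estimated correlation); this turns at total UMI scaling, with 10 higher and 2 lower. The counts adjusted over the list alone were the same for these lists.

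In the other hepatocyte lists most members that passed were lower at TMM scaling, but none of these lists passed with an estimated correlation. All 8 hepatocyte secreted-protein genes were lower (median -1.42; Serpina3k by -3.54 ± 0.22, Fgb by -2.23 ± 0.14, Apob by -1.45 ± 0.18; adjusted p = 0.137 with an estimated correlation), and 6 were lower and 1 higher at total UMI scaling. Of 16 bile acid genes 12 fell, among them the sterol hydroxylase gene Cyp8b1 (-3.42 ± 0.18) and the bile acid uptake gene Slc10a1 (-2.78 ± 0.16), and Abcb4 rose (adjusted p = 0.0526 with an estimated correlation); at total UMI scaling 9 were lower and 5 higher. Of 11 urea cycle and ammonia genes 10 fell (Nags by 1.52 ± 0.10, Otc by 1.55 ± 0.11, Asl by 2.20 ± 0.19; adjusted p = 0.0759 with an estimated correlation), of which 6 members were lower and 1 higher at total UMI scaling. Of 14 gluconeogenesis and amino acid genes 13 fell (among them Fbp1 by 1.07 ± 0.09 and Hal by 2.42 ± 0.21) and Ppargc1a rose (adjusted p = 0.0769 with an estimated correlation); at total UMI scaling 7 were lower and 1 higher. Of 16 methionine, choline and one-carbon genes 12 fell, with Shmt1 at -1.43 ± 0.09, Dmgdh at -1.82 ± 0.11 and Cbs at -2.11 ± 0.14, and 2 rose, Mat2a among them (adjusted p = 0.0759 with an estimated correlation); at total UMI scaling 7 were lower and 5 higher. Of 22 xenobiotic metabolism genes 17 fell (Cyp2c29 by 5.08 ± 0.29, Ugt2b5 by 1.81 ± 0.13, Cyp2f2 by 3.33 ± 0.24; adjusted p = 0.0813 with an estimated correlation), against 14 lower and 5 higher at total UMI scaling. Adjusted over the list alone, 13 bile acid genes fell; the other counts adjusted over the list alone were the same.

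Of 17 acute phase genes 14 fell, including the serum amyloid genes Saa2 (-5.30 ± 0.20) and Saa1 (-4.58 ± 0.19) and the fibrinogen gene Fgg (-2.34 ± 0.10; adjusted p = 0.0759 with an estimated correlation); 13 were lower and 1 higher at total UMI scaling. Saa1 and Saa2 are near-identical copies. All 18 complement and coagulation genes fell (C8b by 2.77 ± 0.16, C9 by 1.88 ± 0.12, Mbl2 by 2.61 ± 0.19; adjusted p = 0.127 with an estimated correlation), against 11 lower and 1 higher at total UMI scaling. Of 15 hepatocyte transcription factor genes 11 fell, with Hnf4a at -1.45 ± 0.08 and Foxa3 at -1.93 ± 0.21 (adjusted p = 0.137 with an estimated correlation), but 5 were higher and 2 lower at total UMI scaling. In the unfolded protein list Herpud1 fell by 1.88 ± 0.14 and Creld2 by 1.82 ± 0.23, with 8 of 14 lower, and Atf3 rose by 4.25 ± 0.15 with Ddit3, Trib3, Chac1 and Fgf21 (median -0.81, mean 0.05; adjusted p = 0.793 with an estimated correlation); 5 rose and 3 fell at total UMI scaling. Wnt target genes were 5 higher and 5 lower of 14, with Nkd1 at 0.98 ± 0.15 and Tbx3 at -1.38 ± 0.23 (adjusted p = 0.936 with an estimated correlation), and 10 higher and 0 lower at total UMI scaling. Clock genes were 2 higher and 6 lower of 14, with Npas2 at 1.95 ± 0.32 and Nr1d2 at -0.42 ± 0.07 (adjusted p = 0.549 with an estimated correlation), and 10 higher and 0 lower at total UMI scaling. Of 9 immediate early genes Jun rose by 1.29 ± 0.12 and Klf4 by 1.39 ± 0.25, and Dusp1 fell (adjusted p = 0.939 with an estimated correlation). At total UMI scaling 8 were higher and 0 lower. All 9 mitochondrially encoded genes were lower (median -1.04; adjusted p = 0.57 with an estimated correlation), but 0 of them passed at total UMI scaling (median -0.21), and 4 passed within number block 1 (median -0.47) against 9 within number block 2 (median -1.73). Counts adjusted over the list alone differed for transcription factors, of which 1 rose, and were otherwise the same.

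**Figure D1:**
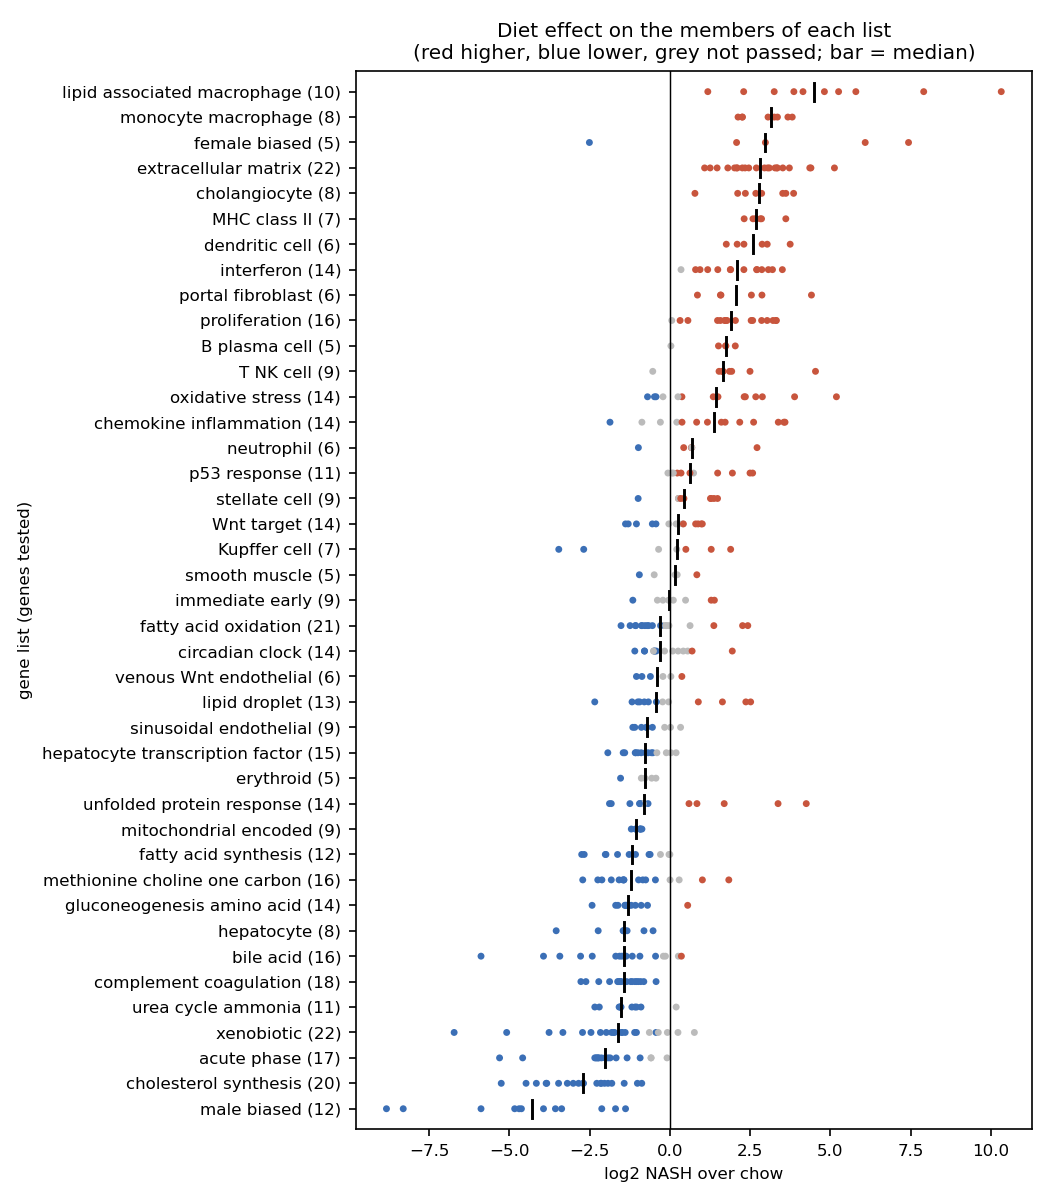
Log2 change, NASH over chow, of each tested member of the gene lists (points), from TMM-scaled section sums of 6 chow and 7 NASH sections. The lipid-associated macrophage and extracellular matrix members lie above 0 and the cholesterol synthesis and male-biased members below it; at total UMI scaling the median of all genes moves from 0.03 to 0.91, which turns lists that lie close to 0.

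In all, 9665 of 14624 genes (66.1%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 5168 higher and 4497 lower in NASH, of which 3292 and 1092 changed at least 2-fold. The values of 6274 genes did not overlap between the 2 diets, 42.9% of those tested against 0.117% by chance if the 13 sections were independent. Summed per likely mouse (3 against 4), 10252 of 15992 genes (64.1%) did not overlap, against 5.71% by chance. Within number block 1 (3 against 3) 8063 genes passed and within number block 2 (3 against 4) 10262; 7337 passed in both blocks in the same direction, 12 in opposite directions, and 2763 would be shared by independent lists. However, sections n and n + 3 of a diet are likely from the same mouse, so the blocks repeat the same animals. At total UMI scaling 11725 genes were higher and 730 lower, and 2037 of the genes called at TMM scaling were called the opposite way. Without NASH sections 4 to 7, 8288 genes passed, 7684 of them in common. Since sections share mice, these p-values are too small. With counts summed per likely mouse (3 against 4) 10143 genes passed, 9140 of them in common.

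**Figure D2:**
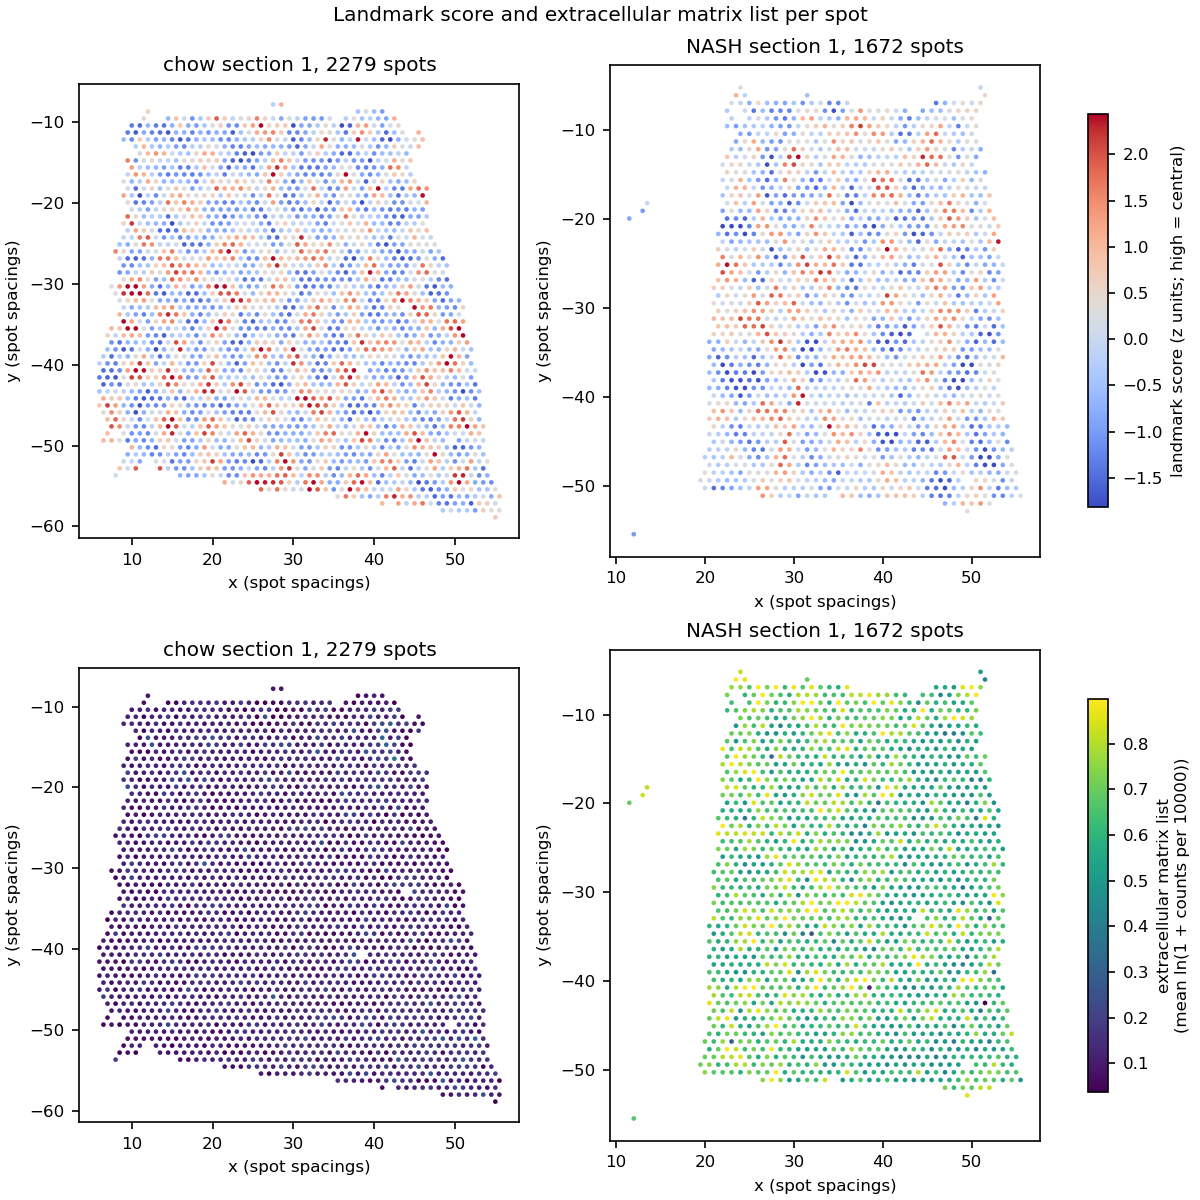
Spots of chow section 1 (2279 spots) and NASH section 1 (1672 spots) in spot spacings, coloured by the landmark score (upper maps; high is central) and by the mean ln(1 + counts per 10000) of the extracellular matrix list (lower maps). Central and portal spots alternate in patches in both sections, and the matrix list is higher across the NASH section.

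The second comparison asked which genes differ between the central and the portal zone in each diet. In chow the central zone was highest over the portal zone for the ornithine aminotransferase gene Oat (log2 2.91 ± 0.22), Serpina7 (2.88 ± 0.14), Slc13a3 (2.87 ± 0.17), Cyp2a5 (2.86 ± 0.14), Lhpp (2.65 ± 0.23), Aldh3a2 (2.57 ± 0.12), Cyp2c29 (2.40 ± 0.13) and the glutamine synthetase gene Glul (2.37 ± 0.16). The most portal genes were the osteopontin gene Spp1 (-2.50 ± 0.17), Cib3 (-2.19 ± 0.18), Hsd17b6 (-2.04 ± 0.13), Tstd1 (-1.76 ± 0.13), Etnppl (-1.67 ± 0.12), Slc3a1 (-1.64 ± 0.10), Nrg4 (-1.63 ± 0.12) and Gls2 (-1.51 ± 0.13). All 16 had the same sign in 6 of 6 chow sections. By edgeR's test 4269 of 13700 genes were zonated in chow, 1799 central and 2470 portal, 557 of them at least 2-fold. In NASH 3626 were, 1758 central and 1868 portal, 197 of them at least 2-fold. Central in both diets were 590 genes, against 231 for independent lists, and portal in both 913 against 337; 108 went from central to portal and 246 from portal to central. Within number block 1 the counts were 2425 in chow and 1259 in NASH, and within number block 2 3461 and 3163. At total UMI scaling the chow split was 4219 central and 1094 portal and the NASH split 3188 and 1009. Sections share mice, so these p-values are too small.

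Central landmark genes differed less between the zones in NASH. The ethanol-oxidizing cytochrome gene Cyp2e1 went from 2.45 ± 0.12 in chow to 0.40 ± 0.10 in NASH, a difference of -2.04 ± 0.15 (adjusted p = 3.7e-09). Lect2 changed by -1.60 ± 0.17, Cyp2a5 by -1.42 ± 0.18, Gulo by -1.37 ± 0.15, Cyp2c37 by -1.35 ± 0.25, Cyp1a2 by -1.07 ± 0.17 and Rgn by -1.04 ± 0.16. The differences of Glul, at 2.37 ± 0.16 and 2.18 ± 0.15 (adjusted p = 0.59), Oat, at 2.91 ± 0.22 and 2.50 ± 0.20 (adjusted p = 0.34), and the glutamate transporter gene Slc1a2, at 2.93 ± 0.23 and 2.74 ± 0.22 (adjusted p = 0.73), did not pass. Both Glul and Oat depend on the setting. They were less central in NASH with the replicate number as a block (-0.29 ± 0.06 and -0.47 ± 0.07), which was not shown to pair sections, without the low-count filter and within number block 2, and Oat with a number block term. They did not pass within number block 1 or with counts summed per likely mouse (-0.15 and -0.47). Portal landmarks went both ways. The urea cycle genes Arg1 (-0.59 ± 0.08 to -1.59 ± 0.07) and Ass1 (-0.48 ± 0.06 to -1.13 ± 0.06) became more portal, and so did Cyp2f2, Hal, Sds and Pck1, of which Pck1 did not pass with DESeq2 (-0.52) or within number block 1 (-0.38). Ctsc, a protease gene of hepatocytes and macrophages, turned from -1.54 ± 0.13 to 0.33 ± 0.11, and Cdh1 went from -1.81 ± 0.19 to -0.80 ± 0.15. Across the 16 central landmarks the mean central over portal value was 2.23 ± 0.558 in 6 chow and 1.31 ± 0.321 in 7 NASH sections (exact permutation p = 0.00932). Across the 16 portal landmarks it was -1.44 ± 0.446 and -1.55 ± 0.323 (exact p = 0.624). Both p-values are too small because sections share mice.

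**Figure D3:**
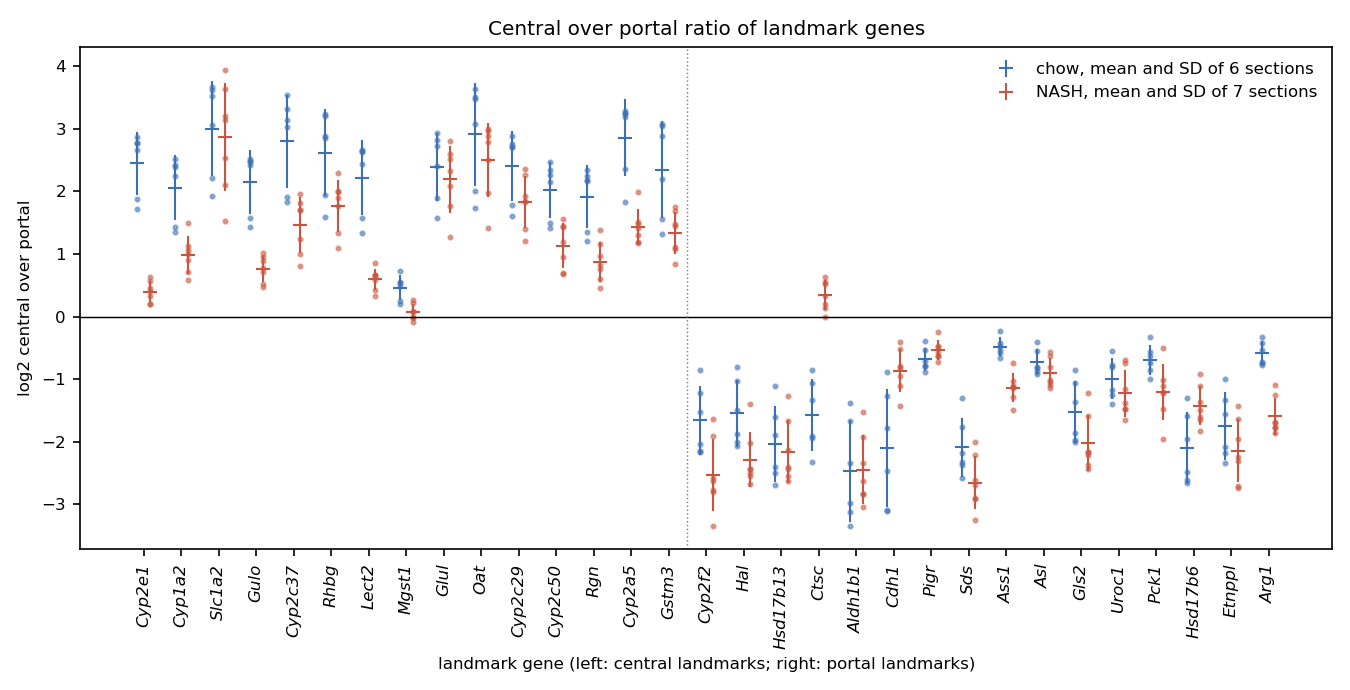
Log2 central over portal of landmark genes per section (points), with mean and SD of 6 chow and 7 NASH sections, each measured in zones ranked by the landmark set that does not hold it. The fitted values are 2.45 in chow and 0.40 in NASH for Cyp2e1, 2.37 and 2.18 for Glul, and -1.54 and 0.33 for Ctsc.

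The third comparison tested the difference in zonation itself. The genes that moved most towards the central zone in NASH were Spp1 (difference 2.08 ± 0.22, from -2.50 to -0.42), the scavenger receptor gene Marco (2.03 ± 0.23, from -0.91 to 1.11), Cib3 (1.62 ± 0.20), Saa3 (1.60 ± 0.11, from -0.75 to 0.85), Clec4f (1.44 ± 0.22), Mup20 (1.33 ± 0.12), Vsig4 (1.25 ± 0.18) and Cd5l (1.15 ± 0.15). Those that moved most towards the portal zone were Serpina7 (-2.18 ± 0.17, from 2.88 to 0.70), Slc13a3 (-1.85 ± 0.21), Mup9 (-1.81 ± 0.31), Cyp4a10 (-1.74 ± 0.26), Cyp2c68 (-1.65 ± 0.12, from 1.69 to 0.04), Cyp2c54 (-1.61 ± 0.19), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.56 ± 0.12, from 1.42 to -0.13), and Aldh3a2 (-1.54 ± 0.16). The Cyp2c and Mup genes have near-identical copies. All 16 differences had adjusted p-values of 1.6e-04 or below, Mup9 having the highest. The test called 2764 of 13700 genes, 1411 more central and 1353 more portal in NASH, 347 of them by at least 2-fold; at total UMI scaling the split was 997 and 2083. Within number block 1 it called 793 genes and within number block 2 2375. Genes central in chow of number block 1 (968) were taken to block 2, which holds other sections but likely the same chow mice: 446 were less central in NASH and 14 more, with medians of 0.50 in chow and 0.17 in NASH. For the 1433 portal genes chosen in block 1, 484 were less portal and 84 more, with medians of -0.35 and -0.13. In the other direction, 256 of 1647 central genes were less central and 8 more (medians 0.23 and 0.06), and 302 of 1795 portal genes were less portal and 30 more (medians -0.29 and -0.10). These choices leave out genes zonated only in NASH. Over all sections, the 1758 genes central in NASH had medians of 0.313 in NASH and 0.0627 in chow, with 606 called more central in NASH. The 1868 genes portal in NASH had -0.252 and -0.145, with 516 called more portal. The p-values are too small since sections share mice. With counts summed per likely mouse, 2328 genes were called, 2263 of them in common.

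Kupffer cell genes moved as a group: all 7 became more central, from a median of -0.49 in chow to 0.84 in NASH (adjusted p = 0.0832 with an estimated correlation). Timd4 went from -0.54 ± 0.11 to 1.02 ± 0.24 and Adgre1 from -0.29 ± 0.13 to 0.54 ± 0.08. All 7 MHC class II genes became more central, such as Cd74 (-0.43 ± 0.05 to 0.32 ± 0.05; adjusted p = 0.0832 with an estimated correlation), as did 4 of 8 monocyte and macrophage genes, Lyz2, Cd68, Fcgr1 and Cd14, against Cx3cr1 (adjusted p = 0.149 with an estimated correlation). Of 10 lipid-associated macrophage genes 4 became more central, Spp1, Lgals3, Fabp5 and Cd63 (adjusted p = 0.307 with an estimated correlation). Of 8 cholangiocyte genes 6 became less portal, among them Cldn7 (-2.88 ± 0.26 to -0.34 ± 0.09), with a list median of -2.24 in chow and -0.39 in NASH (adjusted p = 0.0978 with an estimated correlation). Of 6 portal fibroblast genes 4 became more central, Dpt, Thy1, Fbln2 and Mfap4 (adjusted p = 0.0832 with an estimated correlation), as did 7 of 9 immediate early genes, such as Jun (-0.27 ± 0.07 to 0.20 ± 0.05; adjusted p = 0.0978 with an estimated correlation), and 9 of 20 cholesterol synthesis genes, such as Sqle (-0.82 ± 0.07 to 0.25 ± 0.19; adjusted p = 0.307 with an estimated correlation). Adjusted over the list alone, 7 cholangiocyte and 13 cholesterol synthesis genes became more central; the other counts adjusted over the list alone were the same. Cell type markers moved apart: 4 of 9 sinusoidal endothelial genes became more portal (Kdr and Dnase1l3 with Stab2 and Clec4g; adjusted p = 0.33 with an estimated correlation), and so did Rspo3, Thbd and Selp of the 6 venous endothelial genes (adjusted p = 0.232 with an estimated correlation).

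In several hepatocyte lists more members became more portal than more central. Of 21 fatty acid oxidation genes 17 became more portal and 0 more central (adjusted p = 0.174 with an estimated correlation), and the list median went from 0.26 to -0.03. Of 15 bile acid genes 10 became more portal, such as Cyp8b1 (0.57 ± 0.08 to -0.90 ± 0.10) and Slc10a1, and Cyp7b1 and Abcb11 more central (adjusted p = 0.0948 with an estimated correlation). Of 11 urea cycle genes 7 became more portal (Otc from -0.34 ± 0.05 to -0.65 ± 0.05; adjusted p = 0.0832 with an estimated correlation), of 16 methionine and choline genes 10 (Shmt1 from 0.08 ± 0.05 to -0.29 ± 0.05; adjusted p = 0.149 with an estimated correlation), of 18 xenobiotic genes 11 (adjusted p = 0.174 with an estimated correlation) and of 10 Wnt target genes 5, such as Tbx3 (2.46 ± 0.10 to 1.45 ± 0.11; adjusted p = 0.174 with an estimated correlation). The exceptions that became more central were Chka and, among xenobiotic genes, Gstp1 and Aox3. The difference of Otc did not pass within number block 1 (-0.22) or with spots thinned to 5000 UMIs (-0.23). Adjusted over the list alone, the counts of more portal genes were 18 for fatty acid oxidation, 11 for bile acids, 8 for the urea cycle, 11 for methionine and choline, 12 for xenobiotics and 5 for Wnt targets. Of 22 extracellular matrix genes 2 became more central (Timp1 and Thbs1) and 3 more portal (Col3a1, Lum and Bgn) (adjusted p = 0.962 with an estimated correlation). The p-values of all these zone tests are too small since sections share mice.

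The other lists are given as members more central and more portal in NASH, with the p of the list. Male-biased genes had 5 and 1 of 12 (adjusted p = 0.174 with an estimated correlation), acute phase genes 6 and 2 of 17 (0.332), chemokine genes 6 and 0 of 14 (0.174), unfolded protein genes 7 and 2 of 14 (0.174), gluconeogenesis genes 1 and 5 of 12 (0.278), hepatocyte transcription factors 2 and 5 of 15 (0.278), mitochondrial genes 0 and 3 of 9 (0.46) and smooth muscle genes 2 and 0 of 5 (0.334). Fatty acid synthesis genes had 5 and 6 of 12 (0.832), lipid droplet genes 2 and 5 of 13 (0.682), hepatocyte genes 2 and 3 of 8 (0.881), complement genes 4 and 8 of 18 (0.683), stellate cell genes 2 and 3 of 9 (0.718), oxidative stress genes 3 and 3 of 14 (0.947) and p53-response genes 2 and 1 of 11 (0.415). Proliferation genes had 1 and 1 of 16 (0.791), and neutrophil (0.232), B cell (0.564) and interferon genes (0.984) had 1 member each, S100a9, Cd79b and Irf7, more central. By edgeR's test, no member of the T and NK cell (0.499), dendritic cell (0.499), erythroid (0.571), female-biased (0.46) or clock list (0.83) passed. Adjusted over the list alone, counts differed by at most 2 genes from these.

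Zonal structure was also measured without zones. The correlation across spots between both landmark scores was 0.793 ± 0.0948 in chow (SD, n = 6) and 0.695 ± 0.104 in NASH (n = 7; two-sided exact permutation p = 0.113). The sections overlapped, and the means were 0.726 and 0.613 within number block 1 (exact p = 0.3) and 0.859 and 0.756 within number block 2 (exact p = 0.0571, the smallest possible there). Without thinning the difference was -0.113 (exact p = 0.00233). Moran's I of the landmark score was 0.600 ± 0.0651 in chow and 0.627 ± 0.0849 in NASH (exact p = 0.509), with 0.563 and 0.548 within block 1 (exact p = 0.7) and 0.636 and 0.687 within block 2 (exact p = 0.0571). These p-values are too small since sections share mice.

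Along the central to portal axis, the score of the lipid-associated macrophage list went from a Spearman rho of -0.105 ± 0.0433 with the central score in chow (SD, n = 6) to 0.169 ± 0.107 in NASH (n = 7), and that of the Kupffer cell list from -0.128 ± 0.0364 to 0.276 ± 0.167. Of the former list, Gpnmb, Mmp12, Itgax and Trem2 had only 94, 258, 256 and 645 UMIs over the chow sections. Its member Spp1 was the most portal gene named in chow. The chow rho of this list thus says little about where such macrophages lie. The MHC class II list went from -0.0341 ± 0.0312 to 0.205 ± 0.0842, the urea cycle list from -0.0163 ± 0.0422 to -0.283 ± 0.0916 and the methionine and choline list from -0.0240 ± 0.0641 to -0.256 ± 0.0721. In these 5 lists the 7 NASH sections lay outside the range of the 6 chow sections, with an exact p of 0.00117, the smallest possible, and an adjusted p of 0.0028 over 12 lists. The acute phase list went from -0.467 ± 0.0957 to -0.233 ± 0.0734 and the xenobiotic list from 0.627 ± 0.0986 to 0.343 ± 0.0800 (exact p = 0.00233, adjusted p = 0.0040). The matrix (0.115 and 0.158, exact p = 0.275), cholangiocyte (-0.113 and -0.0670, exact p = 0.111), stellate cell (0.119 and 0.0790, exact p = 0.203), lipid droplet (0.266 and 0.274, exact p = 0.896) and fatty acid synthesis lists (-0.226 and -0.219, exact p = 0.914) did not pass.

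**Figure D4:**
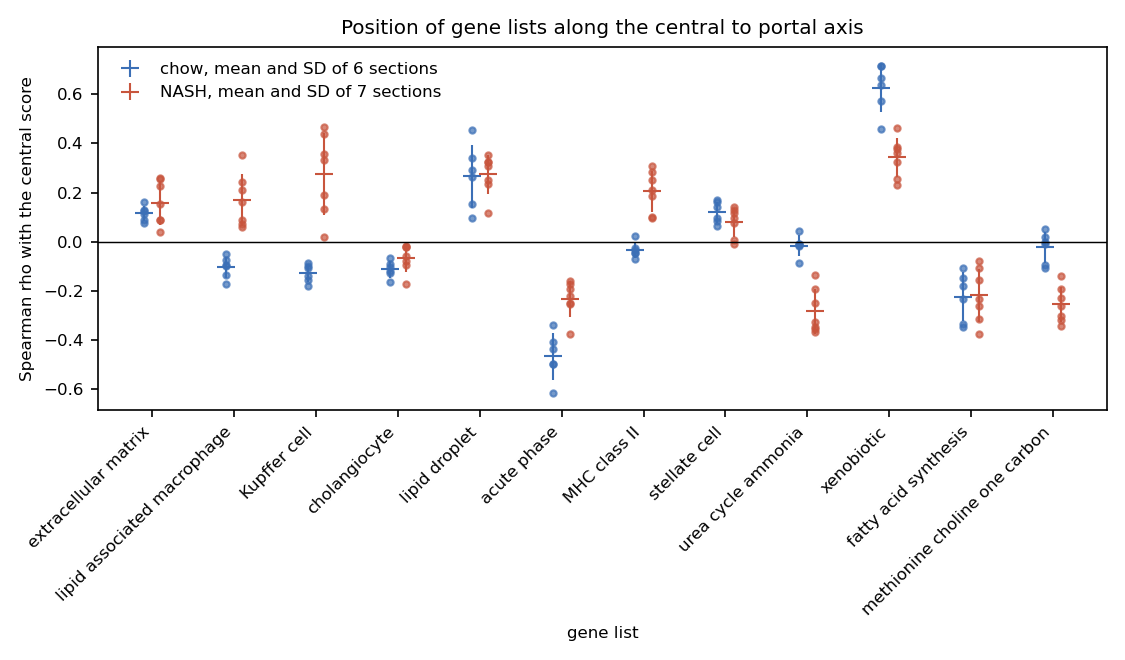
Spearman's rho across thinned spots between each list score and the central landmark score, per section (points) with mean and SD for 6 chow and 7 NASH sections. The Kupffer cell list averages -0.128 in chow and 0.276 in NASH, and the xenobiotic list 0.627 and 0.343.

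Within number block 1 (3 against 3) the differences of these 7 lists were 0.197 for lipid-associated macrophages, 0.280 for Kupffer cells, 0.155 for MHC class II, -0.198 for the urea cycle, -0.168 for methionine and choline, 0.219 for the acute phase and -0.250 for xenobiotics, each at the smallest exact p of 0.1. Within number block 2 (3 against 4) they were 0.340, 0.502, 0.305, -0.314, -0.279, 0.263 and -0.328, each at the smallest exact p of 0.0571. Averaged per likely mouse (3 against 4) they were 0.283, 0.428, 0.245, -0.273, -0.238, 0.232 and -0.296, each again at the smallest exact p of 0.0571. The p-values over all 13 sections are too small since sections share mice.

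The scores of matrix and macrophage genes were correlated across spots in NASH more than in chow. The rho across spots between the extracellular matrix and lipid-associated macrophage lists was 0.0546 ± 0.0334 in chow (SD, n = 6) and 0.432 ± 0.0754 in NASH (n = 7), that between lipid-associated macrophages and Kupffer cells -0.00698 ± 0.0161 and 0.276 ± 0.0825, that between lipid-associated macrophages and lipid droplets -0.0342 ± 0.0288 and 0.138 ± 0.0674, and that between matrix and cholangiocytes 0.0314 ± 0.0206 and 0.150 ± 0.0364. For these 4 pairs every NASH section was above every chow section (exact p = 0.00117, the smallest possible; adjusted p = 0.00146 over 5 pairs). Matrix and lipid droplets also passed over all sections, at 0.0350 ± 0.0197 and 0.110 ± 0.0723 (exact permutation p = 0.0326). The differences within number block 1 were 0.314, 0.261, 0.137 and 0.102 for the 4 pairs, each at the smallest exact p of 0.1, and within number block 2 0.424, 0.298, 0.203 and 0.130, each at the smallest exact p of 0.0571. For matrix and lipid droplets they were 0.0577 (exact p = 0.4) and 0.0885 (exact p = 0.229). Per likely mouse (3 against 4) the 4 pairs differed by 0.385, 0.291, 0.180 and 0.119, each at the smallest exact p of 0.0571. Matrix and lipid droplets differed by 0.0785 (exact p = 0.229). Lists near the floor in chow give a rho close to 0 there, and sections share mice, so the p-values over all 13 sections are too small.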

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

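The counts over other splits of the sections were chosen beforehand, while the grouping of sections into mice, the tests that weigh the Kupffer cell and landmark patterns and the comparison of block differences in the mitochondrial share were chosen only after the result was seen. Since sections share mice, every p-value over sections here is too small.

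Zonation differed between the diets for 2764 genes. The largest differences of central over portal, NASH minus chow, were 2.08 for Spp1, 2.03 for Marco, 1.62 for Cib3, 1.60 for Saa3, 1.44 for Clec4f, 1.33 for Mup20, 1.25 for Vsig4 and 1.15 for Cd5l. Towards the portal zone they were -2.18 for Serpina7, -1.85 for Slc13a3, -1.81 for Mup9, -1.74 for Cyp4a10, -1.65 for Cyp2c68, -1.61 for Cyp2c54, -1.56 for Cyp7a1 and -1.54 for Aldh3a2. Chance is an unlikely origin of the 2764 genes, though splits of sections that share mice cannot exclude it. Among 60 splits of the sections into 6 and 7, only the real one, 1 of 60, gave as many, and the highest other gave 881. The split by number block gave 4 genes. It mixes the diets on both sides, so it does not show that zonation is alike in the blocks. The central over portal value of Glul was 1.58 to 2.41 in chow sections of block 1 and 2.72 to 2.93 in those of block 2. In NASH sections it was 1.28 to 2.08 and 2.33 to 2.80. Of the 64 splits that part all same-numbered pairs, 1 gave as many, the real one, and the highest other gave 870. With counts summed per likely mouse, 1 of 35 splits into 3 and 4, the real one, gave as many as 2328 genes, and the highest other gave 6.

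Kupffer cell genes lay on the portal side in chow and on the central side in NASH, with a mean central over portal value of -0.551 ± 0.237 and 0.892 ± 0.557 (SD, n = 6 and 7; difference 1.44, exact permutation p = 0.00117, the smallest possible; per likely mouse 1.55, exact p = 0.0571, the smallest that 3 against 4 allows). Ranking the zones by the other landmark set gave a difference of 1.56, and thinning every spot to 5000 UMIs gave 1.33 (exact p = 0.00117 each), which argues against the choice of landmarks and against sequencing depth as the whole cause. A lower hepatocyte share in central spots would raise the genes of all other cell types alike. The Kupffer cell list moved by 1.61 more than the sinusoidal endothelial list (exact permutation p = 0.00117). The endothelial (-0.166) and stellate cell lists (-0.0403) did not move towards the central zone. The cholangiocyte (1.38), MHC class II (0.598), lipid-associated macrophage (0.481) and monocyte and macrophage lists (0.476) did. The comparison with 1 list thus cannot exclude a lower hepatocyte share as part of the cause. A hypothesis that stays open is that resident macrophages may be lost near portal tracts, gained or retained near central veins, or change their expression by position. These were not told apart here, since spots hold several cells.

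Central landmark genes were flatter in NASH (2.23 ± 0.558 and 1.31 ± 0.321; SD, n = 6 and 7), while the portal mean did not differ by the test (difference -0.111, exact p = 0.624), which alone decided nothing. A less accurate zone ranking in NASH would flatten landmarks on both sides and steepen none. By edgeR's test 6 of the 32, all portal, were steeper in NASH (Pck1 not with DESeq2), which argues against it as the whole cause. In turn, 13 central and 3 portal landmarks were flatter. This criterion replaced earlier ones after results were seen. Without thinning, the correlation between both landmark scores was 0.913 ± 0.0287 in chow and 0.801 ± 0.0404 in NASH (exact permutation p = 0.00233). With spots thinned to 5000 UMIs it was 0.793 and 0.695 (exact permutation p = 0.113). A less accurate ranking as part of the cause thus stays open. With spots thinned to 5000 UMIs the difference of the 8 central landmarks measured there was -0.769 (exact p = 0.0233), against -0.748 for the same 8 genes without thinning (exact p = 0.021), which argues against depth as the whole cause. One candidate explanation that stays open is a loss of central expression in hepatocytes. Changes in the cell mixture of central spots were not tested for these genes.

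The mitochondrial share of counts was lower in the NASH sections of number block 2 than in those of number block 1, by -2.15 percentage points, against 0.0855 points in chow. A library batch acting alike on both diets would give equal differences, but they differed by -2.24 points (permutation p = 0.0329 over 700 splits within diets). These splits shuffle the blocks within each diet, so this p tests for no block difference in either diet, not for equal differences. The sections ran from 3.81% to 3.98% in block 1 and from 1.69% to 1.83% in block 2 in NASH. In chow they ran from 2.46% to 3.55% and from 2.42% to 3.76%. A diet effect limited to mitochondrially encoded genes was tested by an interaction of diet and number block, which edgeR found in 0% of 14587 nuclear genes and also in 0 of 37 mitochondrial genes, with 1638 of all genes at an unadjusted p under 0.05. DESeq2 found it in 118 nuclear genes (0.809%) and 11 mitochondrial genes. As edgeR's test missed the mitochondrial genes too, it could not decide; differences in the handling of the NASH sections stay open and untested, as do differences between mice, though sections n and n + 3 are likely from the same mouse.

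Single sections stood apart in 16 of 432 groups of 6 or 7 values, by the gap to the nearest other section relative to the range; chance marks about 5% of groups. Among log2 CPM values in chow, section 3 was highest for Atp6v0d2 (0.59, others 0.07 to 0.26) and C9 (9.20, others 8.93 to 9.02), and section 6 for Cyp2b13 (-3.45, others -4.26). Chow section 5 was lowest for Mup1 (10.91, others 11.54 to 11.72), section 2 for Nr1d2 (6.22, others 6.35 to 6.39), and section 4 for Hba-a2 (5.95, others 7.87 to 8.74) and Ciita (-1.77, others -0.63 to -0.31). Among NASH sections, section 1 was lowest for Mup16 (1.45, others 3.05 to 4.13), and section 3 for Flt3 (-0.11, others 0.83 to 1.10) and Tbx3 (2.56, others 2.81 to 2.97). NASH section 5 was lowest for Cxcl16 (5.74, others 6.00 to 6.20) and Ccna2 (1.28, others 1.65 to 1.90), and section 7 for C8b (6.03, others 6.54 to 6.88). For log2 central over portal, NASH section 4 was highest for Cyp2a5 (1.99, others 1.17 to 1.51) and lowest for Spp1 (-0.99, others -0.50 to -0.21), and chow section 5 was highest for Saa3 (-0.29, others -0.90 to -0.77).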

How the results depend on the processing

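Total UMI scaling, the likely mice and the comparison of the section quality measures within blocks were chosen only after seeing the data; the other settings named here were fixed beforehand. Of 8810 comparisons of a result with another setting, 8571 kept direction and side of the threshold. Of the 4725 for the 182 genes named by diet, 4667 did. Genes called by diet ran from 9223 to 9747 with each section left out in turn and from 8063 to 12455 over 13 other settings. With sections left out, zonated genes ran from 3674 to 4267 in chow and from 3007 to 3677 in NASH, and zonation differences from 2291 to 2753; 12 of 14 other settings lay within 1.5 times the reported count in each. Except where its construction is named, the cause was not tested for any change below.

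Total UMI scaling shifts all genes by construction. It gave 11725 genes higher and 730 lower in NASH, 6695 and 286 of them at least 2-fold, where TMM scaling gave 5168 and 4497, with 3292 and 1092. The log2 values of Oit3 (0.0174), Clec4g (0.20), Thbd (0.30), Myl9 (0.43), Hbb-bs (0.0861), Hba-a2 (0.29), Hba-a1 (0.43), Rxra (0.20), Nr1d2 (0.46), Clock (0.40) and Cry1 (0.10) turned positive, of which Rxra, Nr1d2 and Clock passed. Zonated genes became 4219 central and 1094 portal in chow and 3188 and 1009 in NASH, and 2083 differences pointed to the portal zone. Nags (0.10) and Slc25a15 (0.0361) turned in chow, and the difference of Slc3a1 (-0.0122) turned.

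Within number block 1, with fewer sections, 2425 genes were zonated in chow (988 central, 1437 portal), 1259 in NASH (578 and 681), and 793 differed (390 and 403), of which 757 were also called over all sections. Acta2 was at -0.0555 by diet, and the differences of Slc3a1 and Nags were -0.0591 and 0.000513, none of which passed, as in all sections. Acta2 passed within block 2 (0.73) and at total UMI scaling (1.14). The difference in mitochondrial share was 1.04 percentage points, and that in Moran's I -0.0146. The position of the matrix list differed by -0.00450 in block 1, and that of the lipid droplet list by -0.00756 in block 2.

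The 7 list positions and 5 list pairs that passed over all sections cannot pass within a block, where 3 against 3 allows no p below 0.1 and 3 against 4 none below 0.0571. The same holds for the 3 and 4 likely mice. The position differences in block 1, in block 2 and per likely mouse were 0.197, 0.340 and 0.283 for lipid-associated macrophages, 0.280, 0.502 and 0.428 for Kupffer cells, 0.219, 0.263 and 0.232 for the acute phase, 0.155, 0.305 and 0.245 for MHC class II. They were -0.198, -0.314 and -0.273 for the urea cycle, -0.250, -0.328 and -0.296 for xenobiotics and -0.168, -0.279 and -0.238 for methionine and choline. For the pairs they were 0.314, 0.424 and 0.385 for matrix with lipid-associated macrophages, 0.102, 0.130 and 0.119 for matrix with cholangiocytes, 0.137, 0.203 and 0.180 for lipid-associated macrophages with lipid droplets, and 0.261, 0.298 and 0.291 with Kupffer cells. Matrix with lipid droplets gave 0.0577, 0.0885 and 0.0785, and 0.0372 without thinning, and lost its call in each of these. The fatty acid synthesis position turned to -0.00574 per likely mouse.

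Thinning spots to 5000 UMIs leaves fewer counts, and 1926 genes were then zonated in chow (901 central, 1025 portal) and 1402 in NASH (670 and 732). Differences fell to 894 (416 and 478), of which 849 were also called without thinning, and those of Nrg4 (-0.0203) and Nags (0.00539) turned without passing. Zones by the second landmark set turned Cyp2c68 (-0.0634) and Glud1 (-0.0367) in NASH and the differences of Slc3a1 (-0.25) and Nrg4 (-0.13); smoothed scores turned the same values, to -0.0434, -0.0423, -0.25 and -0.13. Zones from the outermost of 4 groups gave -0.0657 for Slc3a1. None of these values passed, with or without the change. With single sections left out, the difference of Slc3a1 ran from -0.0561 to 0.197 and was negative without chow sections 4 (-0.00813), 5 (-0.0374) or 6 (-0.0285) and NASH sections 1 (-0.0200) or 3 (-0.0561). That of Lhpp ran from -0.468 to 0.0527, the highest without NASH section 1, and Glud1 in NASH from -0.00321 to 0.0360, the lowest without NASH section 4.

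Without thinning, the landmark agreement differed by -0.113 and passed, as did the stellate cell position (-0.113), and the positions of the matrix (-0.0135) and lipid droplet lists (-0.0900) turned. The difference in Moran's I was -0.0638 with the first landmark set alone and -0.0180 after thinning to 2000 UMIs. With an estimated correlation 3 lists passed by diet, against 26, and 0 in the zonation difference, against 24 by camera with a preset correlation and 25 by fry.

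The fit with the replicate number as a block (replicate block) called 10154 genes by diet, 4297 zonated in chow, 3255 in NASH and 2548 differences, and 27 and 25 lists. It brought 11 named values past the threshold with the sign unchanged: the differences of Oat (-0.47), Glul (-0.29), Gls2 (-0.47), Etnppl (-0.34) and Lhpp (-0.24), Adgre1 (-0.26) and Folr2 (-0.41) in chow, Mup9 (0.63), Cyp4a10 (0.31) and Cyp2c54 (0.44) in NASH, and Myl9 by diet (-0.45). No other named call changed. With counts summed per likely mouse, 10143 genes were called by diet, 3857 zonated in chow, 3237 in NASH and 2328 differences; Myl9 (-0.50) and the differences of Etnppl (-0.41) and Gls2 (-0.55) passed and Rspo3 (0.32) no longer did. The number block term gave 10686 genes by diet and 2970 differences, and DESeq2 10011 and 2115.

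Named values that kept their direction but lost their call elsewhere were, by diet at total UMI scaling, Retnlg, Kdr, Dnase1l3, Wnt2, Wnt9b, Myh11, Fads1, Dgat2, Acadvl, Cpt2, Tbx3, Oat, Dusp1 and mitochondrial genes. Within block 1 they were S100a9, Wnt9b, Rspo3 and 2 mitochondrial genes, and within block 2 Thbd and Myh11. Among zonation differences, those of Cyp2c29, Pck1, Hsd17b6, Otc and Glud1 lost their call in 1 setting or more, as did Vsig4, Slc25a13 and Glud1 in chow and Spp1 and Timd4 in NASH.

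Single sections decided some calls. By diet, Msln passed without chow section 2 (1.29), Hbb-bs without NASH section 5 (-1.11) and Myl9 without chow section 4 (-0.64) or 6 (-0.60), and S100a9 was lost without chow section 1 (0.38), 4 (0.37) or 5 (0.36) or NASH section 3 (0.39). In chow zonation, Folr2 passed without NASH section 1 (-0.42), 3 (-0.41) or 7 (-0.41) and Adgre1 without NASH section 3 (-0.28). In NASH, Spp1 was lost without NASH section 4 (-0.33). The zonation difference of Gls2 passed without chow section 5 (-0.58) or 6 (-0.58) or NASH section 1 (-0.63) or 3 (-0.57). That of Cyp2c29 was lost without chow section 2 (-0.57), 4 (-0.54), 5 (-0.57) or 6 (-0.57) or NASH section 1 (-0.56) or 3 (-0.51).

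At these depths and spreads the test of the zonation difference recovered 68% of simulated 1.5-fold changes, and the diet test 38%. The simulation changed 200 genes and took sections as independent, so these rates need not hold for the real data. Thinning all sections to the smallest one still called 8907 genes by diet, against 9665, whereas thinning spots to 5000 UMIs called 894 zonation differences, against 2764. In NASH up to 25.7% of the spots of a section were too shallow for that thinning. Changes below 1.5-fold were not simulated, so the simulation sets no limit of detection. Of the 2764 zonation differences called, 347 were at least 2-fold, so smaller ones were called too.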

Other observations

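The split counts over sections below were chosen before the result was seen, and the interaction of diet and number block, the matching of sections and their grouping into mice were added after seeing the data.

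Sections n and n + 3 of a diet deviated together, with correlations across 5437 genes of 0.293 to 0.731. Of the 144 ways to match the sections across the number blocks, 1, this one, gave correlations as high. The matching was chosen after these deviations were seen, so this rank is no independent test of it. In NASH the margin was small: sections 2 and 5, matched, correlated at 0.293, and sections 1 and 7, not matched, at 0.274. This is consistent with the hypothesis that sections n and n + 3 come from the same mouse, since the design gives 2 sections per mouse, but a shared position on the slides was not tested and the labels name no mouse.

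Between the number blocks, the log2 changes by diet of 14529 genes correlated with r = 0.953, a value across genes, which are not independent replicates. Both blocks hold sections of the same mice if that matching is right. No interaction of diet and number block passed in edgeR's test of 14624 genes, where the lowest adjusted p was 0.108 and 1638 genes had an unadjusted p under 0.05, while DESeq2 called 129.

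Chance is an unlikely origin of the 9665 genes that differed by diet. Of 100 splits of the sections into 6 and 7, 1 gave as many, the real one, and the highest other gave 3160. The split by number block gave 1594. Of the 64 splits that part all same-numbered pairs the real one, 1 of 64, gave as many; the highest other, with 6692 genes, put the 6 chow sections with NASH section 7. With counts summed per likely mouse, 1 of the 35 splits into 3 and 4, the real one, gave as many as 10143 genes, and the highest other gave 0. For the number of gene lists that passed with a preset correlation, chance cannot be excluded, since 26 of 100 splits gave at least the 26 lists of the real split and the highest other gave 31. The split by number block gave 1 list. Per likely mouse, 7 of 35 splits gave at least the 27 lists of the real split (highest other 30), and 3 of 35 at least its 22 lists in the zonation difference (highest other 22), so chance cannot be excluded there either. The counts of list members that passed do not rest on that test. Sections that share a mouse make these splits less independent than their number, so no split count here can exclude chance.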
